A study of Danio rerio with 6 samples.

How the data were processed

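Messenger RNA of zebrafish embryos was sequenced in 6 libraries, 3 from a Trdmt1 knockout and 3 from a control group, as the sample titles and genotype labels give them. Per the labels' protocols, total RNA with an integrity number above 7 was made into libraries with the NEBNext Ultra RNA kit for Illumina. The strand setting used in counting is not given in the sources used here, so reads of a gene and of an antisense or overlapping partner cannot be told apart. Per the submitters' processing notes, reads were handled with Trimmomatic 0.30, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq, and the genome build named is Zv9; the notes give no order or settings.

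The deposited table holds one line per Ensembl gene, 31624 in all, with the symbol and annotation terms the authors attached. The columns headed with only a group name and number hold whole numbers per gene and library. They were taken as read counts, not normalized, since the deposited RPKM values can be recomputed from them. Per the file headers, the authors also deposited RPKM values per gene and library, and these equal the counts divided by exonic length and library total in every gene within 0.0051. The exonic length per gene is the deposited value. Every line names a gene. A further 6 columns of per-sample values belong to no sample analysed here and were not used. The table gives no coordinates, so the planned test of genes on the trdmt1 chromosome was not run.

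The planned test for a count table was used. Genes were filtered with edgeR's filterByExpr, which left 20555, libraries were scaled by TMM, and knockout was compared with control by edgeR 4.0.16's robust quasi-likelihood test in R 4.3.3, with no covariate and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The median log2 fold change over all tested genes was -0.00385. Mean and SD are of the deposited RPKM over 3 libraries, and log2 fold changes and standard errors are edgeR's, the latter derived from the F statistic. Library totals of 12877132 to 18721589 reads set the counting precision. The text names trdmt1 and, per direction, up to 12 called genes with the largest log2 fold change that had a mean of at least 1 RPKM in the higher group, knockout libraries all on one side of the controls and a proper symbol. Where fewer passed, genes with the smallest p filled up to 6, which here were also held to the RPKM and separation conditions. Symbols marked as 1 of many copies were treated as placeholders.

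The 42 gene lists for tissues, stress responses and RNA and DNA methylation were fixed before the data were examined, as were the tests and the first set of alternatives. Lists with at least 4 tested members, 41 of them, were tested with limma 3.58.1's camera on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives; the yolk precursor list had 2 tested members and was not tested. List medians per library are of log2 CPM minus the mean of the controls. Annotation terms of 10 to 500 tested genes were tested by one-sided Fisher's exact tests against the 16293 tested genes that carry any term. Library pairs were compared by a chi-square over genes with at least 20 summed reads.

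Alternatives were no filter, a mean RPKM of at least 2, DESeq2 size factors, DESeq2 1.42.0, the replicate number as a block, each library left out, and, chosen after seeing the data, knockouts 1 and 2 summed to 1 sample and each library's trend with exonic length removed by an offset. The procedure was tested on simulated data with 3 libraries per group and the real means and library sizes. The 200 changed genes were drawn from those with higher counts, and a further list with a smaller rise was not counted as false. With the spread of all 6 libraries the procedure recovered 51% of 2-fold and 98% of 4-fold changes in a set of 20555 genes, with 13.8% of calls false. With the spread of the control libraries it recovered 86% and 100%, with 7.18% false. The false share was above the threshold on the adjusted p in both settings. The simulated libraries were drawn independently, without a nearly agreeing pair or an outlying library, so these rates need not hold for the real knockout group.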

Results

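The series measured messenger RNA in zebrafish (Danio rerio) embryos labelled Trdmt1 knockout and in control embryos. Trdmt1, also known as Dnmt2, is an RNA methyltransferase whose known substrates are transfer RNAs, where it methylates a cytosine in the anticodon loop. The stated aim was to examine the function of the gene by comparing the 2 conditions. There were 6 libraries, 3 labelled Trdmt1 knockout and 3 labelled control. The labels used here give no embryo age. They do not say whether the libraries of a group came from separate clutches, so p-values measure only the spread between these samples. Reads counted in genes totalled 18708152, 18721589 and 12877132 in controls 1, 2 and 3. They totalled 15573104, 16085068 and 15191166 in knockouts 1, 2 and 3. Between 17811 and 18431 genes reached 1 RPKM in a library, of 31624 listed.

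The transcript of the targeted gene, trdmt1 (ENSDARG00000034518), stood at 3.10, 2.60 and 1.08 RPKM in controls 1, 2 and 3 and at 1.59, 1.40 and 1.07 RPKM in knockouts 1, 2 and 3. The knockout mean of 1.35 ± 0.263 RPKM (SD, n = 3) was 59.9% of the control mean of 2.26 ± 1.05 RPKM (SD, n = 3). This difference did not exceed the spread between libraries. The log2 fold change was -0.70 with a standard error of 0.38 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.746). A two-sided exact permutation test over the 20 assignments gave p = 0.3, where 0.1 is the smallest p this design allows. Control 3 lay within the knockout range, so the transcript level does not check the labels. A frameshift allele can leave the transcript in place, and the kind of allele is not given in the sources used here.

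Knockout 3 differed from the other 5 libraries in the genes of several tissues. The visual pigment gene rho, rod opsin, stood at 292 RPKM in knockout 3 and between 4.25 and 15.3 RPKM in the other libraries. The trypsin gene try of the exocrine pancreas stood at 56.8 RPKM against 4.31 to 7.36 RPKM. The hatching gland protease gene he1a stood at 15.0 RPKM against 91.1 to 198 RPKM. These 3 genes were chosen after their values were seen. The first principal component, with 45.9% of the variance, set knockout 3 at 84.9 and the other libraries between -21.4 and -13.6. The second, with 22.3%, set knockouts 1 and 2 at -32.8 and -33.3, the controls between 11.5 and 37.6, and knockout 3 at -4.98. Correlations of log2 values across genes, which are not independent replicates, were 0.937 to 0.941 for pairs with knockout 3 and 0.969 to 0.976 for the remaining pairs apart from knockouts 1 and 2. Knockouts 1 and 2 correlated at 0.992, and their counts differed by a chi-square of 1.58 per degree of freedom, against 11.7 to 75.6 in the other 14 pairs. That is more than counting noise, which preparations of a single pool can also show, so it does not make them independent. They were kept as 2 samples as labelled, and counts of called genes with the pair summed to 1 sample are printed beside the main ones.

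**Figure D1:**
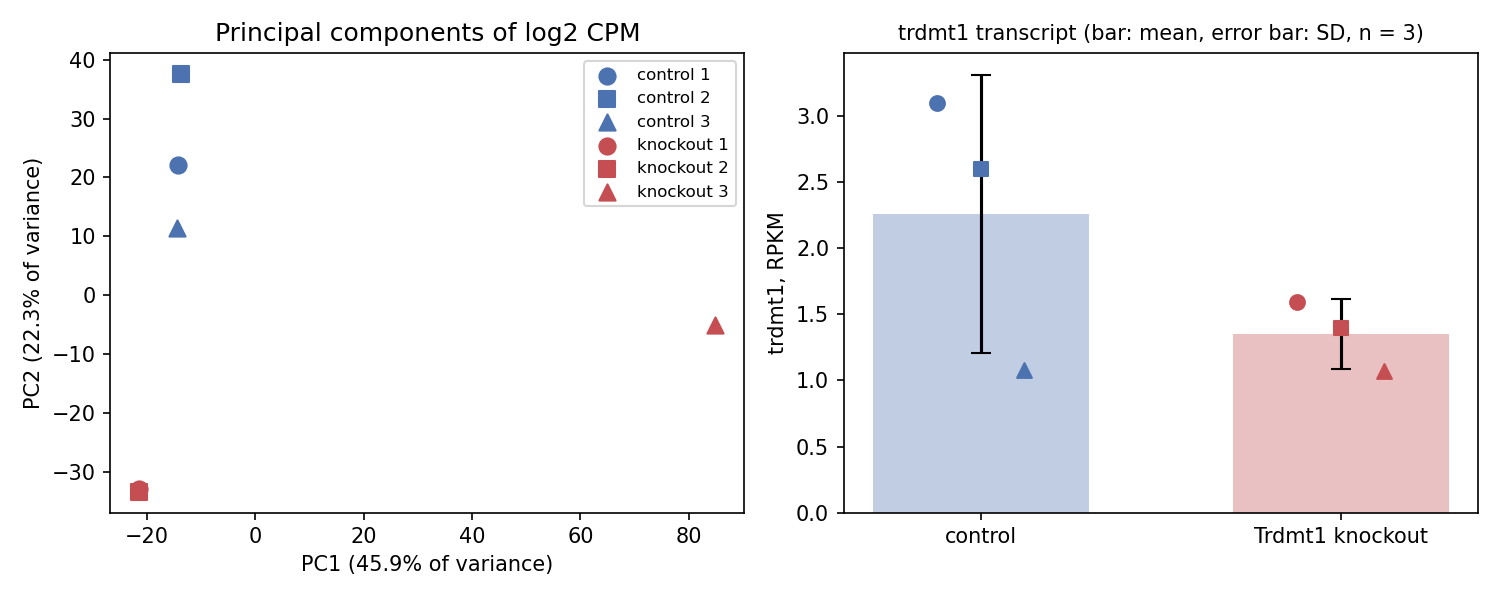
Left, the first 2 principal components of log2 CPM over 20555 genes, 1 point per library, with knockout 3 at 84.9 on the first component and knockouts 1 and 2 on top of each other. Right, trdmt1 in RPKM, with the bar as the mean, the error bar as the SD of 3 libraries and each point as 1 library; control 3, at 1.08 RPKM, lies within the knockout range.

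The main comparison asked which genes differed between knockout and control embryos. Genes for stress- and stimulus-induced transcription factors rose in the knockout libraries. The largest rise with a proper gene symbol was in fosl1a, a Fos family partner in the AP-1 transcription factor, from 1.50 ± 0.685 to 26.7 ± 8.36 RPKM (SD, n = 3 each), 18.4-fold. The related gene fosb rose from 0.970 ± 0.563 to 13.9 ± 4.97 RPKM, 14.4-fold. The stress-induced factor gene atf3, of the ATF family, rose from 7.11 ± 1.38 to 36.2 ± 8.70 RPKM, 5.22-fold. The cell cycle inhibitor gene cdkn1a rose from 5.41 ± 1.08 to 21.0 ± 5.37 RPKM. The gene bhlha9, for a basic helix-loop-helix factor, fell from 10.5 ± 2.91 to 2.62 ± 0.350 RPKM.

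In all, 21 genes were higher and 3 lower in the knockout at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test of 20555 genes, and all 24 changed at least 2-fold. Each of the 24 changed in the same direction when any 1 library was left out. In each of them all knockout libraries lay beyond all controls on the same side, so this outcome was fixed in advance and adds no support. The edgeR adjusted p was 0.0143 for fosl1a and 0.0266 for cdkn1a. The log2 fold change was 3.85 ± 0.41 (SE) for fosb (edgeR adjusted p = 0.0159). It was 2.38 ± 0.22 for atf3 (edgeR adjusted p = 0.0143) and -1.96 ± 0.27 for bhlha9 (edgeR adjusted p = 0.0413). Further transcription factor genes that rose were crema, a cAMP-responsive factor, 4.71-fold, and cebpb, a regulator of inflammatory and metabolic genes, 4.61-fold. The factor genes klf4, ets2 and nr4a3 rose 4.12-fold, 3.91-fold and 3.75-fold. The chemokine gene cxcl18b rose 4.52-fold, cyp24a1, the vitamin D 24-hydroxylase, 4.07-fold, and f3b, a tissue factor gene that starts blood coagulation, 3.94-fold. The edgeR adjusted p of these 8 genes lay between 0.0143 and 0.0413. Outside the rule for named genes, and so named after their values were seen, dusp5, a phosphatase gene of the MAP kinase pathway, rose 2.94-fold. Likewise elf3, an epithelial ETS factor gene, rose 2.84-fold, cldnb, a claudin gene, 2.52-fold, and marco, a macrophage scavenger receptor gene, 3.39-fold. Clone or placeholder names accounted for 5 of the rises and 2 of the 3 falls. The latter were si:dkey-22f5.9, with a log2 fold change of -2.52, and zgc:194839, with -1.56. By the rule, 5 further genes with lower values and the smallest p are given, none past the threshold. The genes pbld2, gramd1c, ddx43, olfm2b and prtfdc1 had log2 fold changes of -1.04, -0.96, -1.28, -1.51 and -1.10, with edgeR adjusted p between 0.118 and 0.161.

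**Figure D2:**
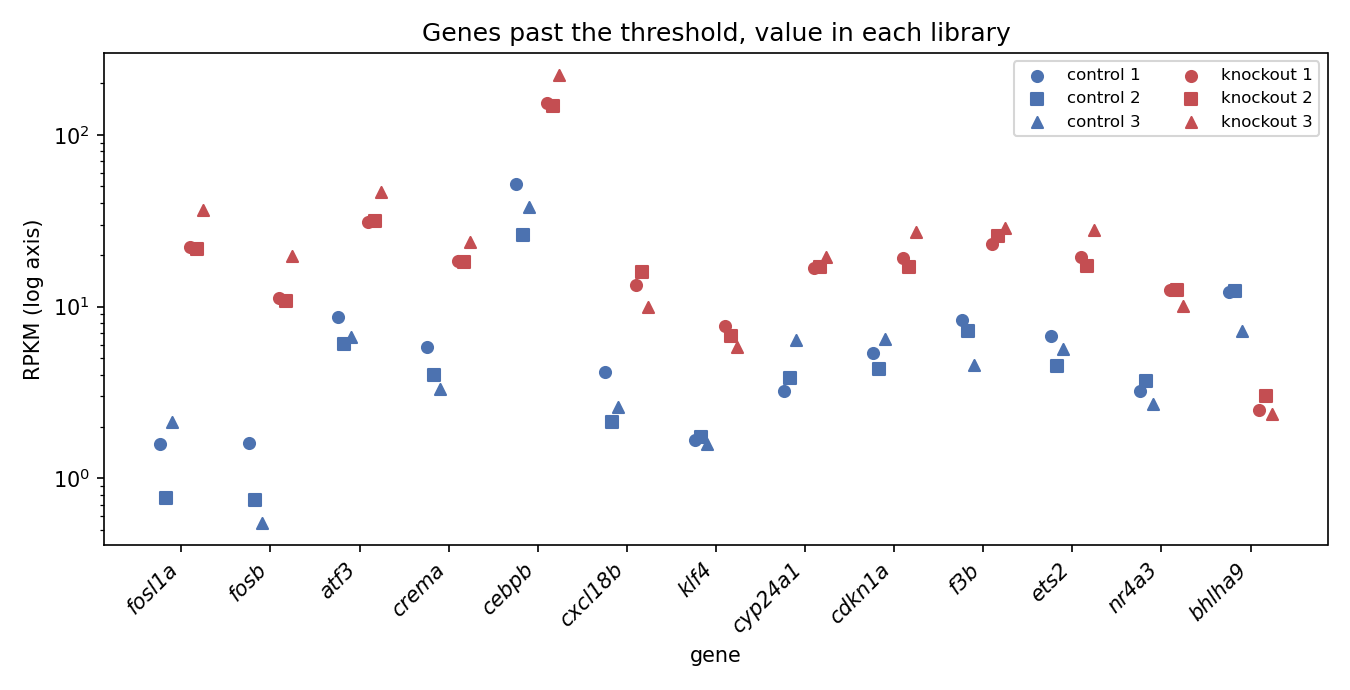
RPKM (log axis) of the 13 genes with a proper symbol that the rule named and that passed the threshold, 1 point per library, controls in blue and knockouts in red. In the 12 genes that rose all 3 knockout libraries lie above all 3 controls, and in bhlha9 all 3 lie below.

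The counts rested on single libraries. Without knockout 3 there were 165 genes higher and 41 lower, among them all 24. Without control 1 there were 7 and 1. Without control 2 there were 0 and 0 by edgeR, although 956 genes had an unadjusted p under 0.05. There were 4 and 0 without control 3, where 1571 genes had an unadjusted p under 0.05. There were 20 and 1 without knockout 1, and 17 and 0 without knockout 2, where 1279 genes had an unadjusted p under 0.05. With knockouts 1 and 2 summed to 1 sample, an alternative chosen after seeing the data, 16 genes were higher, all among the 21. The calls of marco (adjusted p = 0.118), cxcl18b (adjusted p = 0.0718), cldnb (adjusted p = 0.0666) and bhlha9 (adjusted p = 0.0873) were among those lost. The log2 fold changes of the 8 lost calls moved by 0.02 to 0.12, for marco from 1.76 ± 0.25 (SE) to 1.73. None was then lower by edgeR, and 1194 genes in both directions had an unadjusted p under 0.05. DESeq2 on the 6 libraries called 188 higher and 46 lower.

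Annotation terms for transcription from RNA polymerase II promoters, as carried by the deposited table, were enriched among the genes that rose. Of 1515 terms tested, 3 passed, all for higher genes. A term for promoter-proximal DNA-binding transcription factor activity held atf3, fosb and fosl1a among its 12 genes (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.000625). The 2 wider transcription terms held the same 3 genes, with elf3 in 1 of them (adjusted p = 0.0375 for both). No term passed for the 3 genes that fell.

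The second comparison took gene lists fixed before the data were examined. Immediate early genes, which respond within minutes to stimuli, rose as a list: all 18 tested members had positive log2 fold changes, with a median of 1.90. Only fosl1a and fosb passed over all genes tested, and 13 passed when adjusted over the list alone. Among the latter, egr3, an early growth response factor gene, stood at 1.11 ± 0.493 RPKM in controls and 6.72 ± 3.06 RPKM in knockouts (SD, n = 3 each). The orphan nuclear receptor gene nr4a1 stood at 9.40 ± 3.98 and 33.8 ± 17.2 RPKM. The median of the list relative to the control mean was 1.54, 1.34 and 2.74 in knockouts 1, 2 and 3 and 0.76, -0.46 and -0.35 in controls 1, 2 and 3 on the log2 scale. The camera test with a preset correlation of 0.01 gave an adjusted p of 3.24e-19, and adjusted p = 0.271 with an estimated correlation. That estimate was 0.759, far above the preset, so the smaller p-value overstates the evidence. The fry test gave an adjusted p of 0.123.

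Genes of the integrated stress response, the ATF4 program, rose as a list, with a median of 0.57 over 19 members, 16 of them positive. Members atf3 and cebpb passed over all genes and 9 passed adjusted over the list alone. Among these, ppp1r15a, a phosphatase subunit gene that reverses the response, stood at 24.9 ± 4.63 RPKM in controls and 45.3 ± 3.81 RPKM in knockouts, and trib3 at 16.0 ± 3.44 and 27.8 ± 2.32 RPKM (SD, n = 3 each). Its camera adjusted p was 2.81e-09, and adjusted p = 0.235 with an estimated correlation. Knockout 3 had a median of 0.35, against 0.55 to 0.57 in knockouts 1 and 2.

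Heat-shock genes rose as a list of 18, with 12 positive members and a median of 0.28. No member passed over all genes. Adjusted over the list alone, 3 were higher and 1 lower. Among the former, hsp70.2 stood at 3.53 ± 1.90 RPKM in controls and 11.5 ± 1.81 RPKM in knockouts, and hsp70.3 at 6.95 ± 3.64 and 23.1 ± 5.24 RPKM (SD, n = 3 each). The lower one, the small heat-shock gene hspb9, stood at 65.4 ± 16.9 and 34.9 ± 2.16 RPKM. The hsp70 genes are near-identical copies among which reads can be split, so their single values are uncertain. The camera adjusted p was 0.0116, and adjusted p = 0.479 with an estimated correlation. Without knockout 3, whose median was 0.51 against 0.18 and 0.19 in knockouts 1 and 2, the camera adjusted p was 0.0941. It was 0.0673 without control 3 and 0.0544 at a mean RPKM of at least 2.

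Leukocyte genes rose as a list of 22, with 18 positive members and a median of 0.36. The macrophage gene marco passed over all genes and 4 members passed adjusted over the list alone. Besides marco, these were the cytokine gene il1b at 1.12 ± 0.813 RPKM in controls and 9.58 ± 4.41 RPKM in knockouts, the macrophage perforin gene mpeg1.2 at 1.42 ± 0.755 and 4.91 ± 1.64 RPKM, and the neutrophil peroxidase gene mpx at 5.30 ± 0.991 and 8.02 ± 0.855 RPKM (SD, n = 3 each). The camera adjusted p was 1.04e-05, and adjusted p = 0.247 with an estimated correlation. Medians were 0.30, 0.20 and 0.54 in knockouts 1, 2 and 3 and 0.22 in control 1, the highest control.

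Cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, rose as a list, with 18 of 19 positive and a median of 0.36. No member passed over all genes or adjusted over the list alone, although 5 had an unadjusted p under 0.05 by edgeR. The camera adjusted p was 1.07e-05, and adjusted p = 0.566 with an estimated correlation, which was 0.472. The fry adjusted p was 0.392. Knockouts 1, 2 and 3 had medians of 0.26, 0.33 and 0.50, and the controls lay between -0.30 and 0.18. The RNA cytosine methyltransferase list, to which trdmt1 belongs, did not pass (camera adjusted p = 0.786). Of its 9 tested members, nop2, a nucleolar methyltransferase gene, stood at 24.1 ± 3.39 RPKM in controls and 17.7 ± 3.59 RPKM in knockouts. The gene nsun2, whose product methylates tRNAs as Trdmt1 does, stood at 8.81 ± 0.886 and 9.34 ± 1.28 RPKM (SD, n = 3 each). The DNA methylation list did not pass either (camera adjusted p = 0.628).

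Of the tissues that earlier work on this gene in zebrafish had named, liver, brain and retina, no list passed in the main test. Liver genes had a median of 0.03 and a mean of 0.09 but a camera direction of lower (camera adjusted p = 0.76). The 1 member of 24 that passed adjusted over the list alone was hpx, hemopexin, at 0.667 ± 0.0945 RPKM in controls and 0.177 ± 0.0569 RPKM in knockouts (SD, n = 3 each). Neuron genes had a median of 0.12 over 21 members (camera adjusted p = 0.628), with medians of -0.17, -0.14 and 0.54 in knockouts 1, 2 and 3. Photoreceptor and retinal pigment genes had a median of 0.75 over 29 members (camera adjusted p = 0.0659). The list passed with knockouts 1 and 2 summed (camera adjusted p = 0.000231) and with the replicate block (camera adjusted p = 0.0438). Here the knockout libraries went apart, with medians of -0.85, -0.57 and 1.94 in knockouts 1, 2 and 3. Without knockout 3 the photoreceptor list was lower in the knockout, with a median of -0.84 (camera adjusted p = 1.17e-05, and adjusted p = 0.572 with an estimated correlation).

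**Figure D3:**
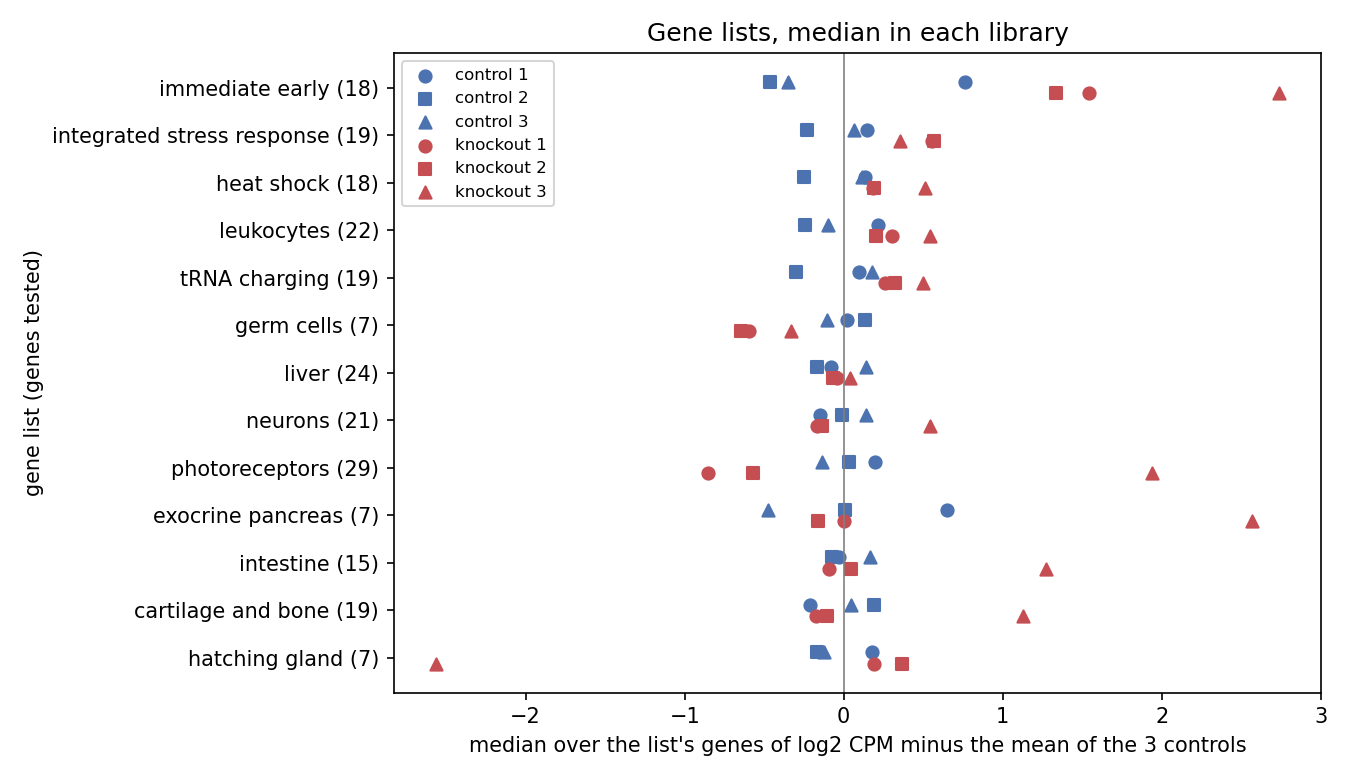
Median over each list's tested genes of log2 CPM minus the mean of the 3 controls (horizontal axis), 1 point per library, controls in blue and knockouts in red, with the number of genes tested in parentheses. Immediate early genes lie at 1.34 to 2.74 in the knockouts and at most 0.76 in the controls, while photoreceptor genes lie at 1.94 in knockout 3 and below the controls in knockouts 1 and 2.

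Of 41 lists tested, 15 passed with camera, 14 higher and 1 lower in the knockout, and 1 of the 14 is not reported singly here. None passed with an estimated correlation. For skeletal muscle, endocrine pancreas and cytochrome P450 genes that estimate was -0.00631, -0.0739 and -0.0133, below the preset of 0.01. So a higher correlation between genes does not account for the failure of these lists in that setting. With fry, which asks whether a list's genes move one way on balance, 4 passed. The list not reported singly was among them, and the others were endocrine pancreas (adjusted p = 0.0485), germ cell genes (adjusted p = 0.0494) and cytochrome P450 and Ahr-response genes (adjusted p = 0.0494). The list that fell was that of germ cell and oocyte genes, 7 tested, with a median of -0.45 (camera adjusted p = 0.00112, and adjusted p = 0.235 with an estimated correlation). On the statistics of DESeq2 it did not pass (camera adjusted p = 0.0515). Its 1 member to pass adjusted over the list alone was ddx4, the germ cell helicase gene vasa, at 0.633 ± 0.107 RPKM in controls and 0.233 ± 0.0306 RPKM in knockouts (SD, n = 3 each). Of 19 genes matched to the list, the 7 tested included others with low values. Control means were 0.187 RPKM for tdrd7a, 0.39 for piwil1, 1.18 for gdf3, 0.347 for tdrd6 and 0.417 for zp3b. The fall of this list thus rests largely on genes near the floor. In the cytochrome P450 list (camera adjusted p = 0.00453, and adjusted p = 0.235 with an estimated correlation), cyp24a1 passed over all genes and 4 members were higher and 1 lower adjusted over the list alone. The lower one was cyp1a, at 36.1 ± 27.6 RPKM in controls and 8.96 ± 3.02 RPKM in knockouts (SD, n = 3 each). The lens list, mostly crystallin genes with near-identical copies, rose with a median of 0.38 over 50 members and none past the threshold (camera adjusted p = 5.87e-07, and adjusted p = 0.611 with an estimated correlation). The 3 controls spanned -0.49 to 0.46, and the knockouts 0.41 to 0.52. The lens list did not pass without control 1 (camera adjusted p = 0.303).

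Glycolysis and gluconeogenesis enzymes had a median of 0.30 (camera adjusted p = 0.000559, and adjusted p = 0.503 with an estimated correlation). The gene pck1, for the first committed enzyme of gluconeogenesis, was the 1 member of 29 to pass adjusted over the list alone. Skeletal muscle genes had a median of 0.17 over 33 members (camera adjusted p = 0.00241, and adjusted p = 0.235 with an estimated correlation). The fast myosin genes myhz1.2 and myhz1.1, similar copies that can share reads, passed adjusted over the list alone. The muscle medians were 0.05, 0.06 and 0.35 in knockouts 1, 2 and 3, and without knockout 3 the median log2 fold change was 0.05 (camera adjusted p = 0.0438). Interferon-response genes had a median of 0.19 over 11 members (camera adjusted p = 0.0076, and adjusted p = 0.479 with an estimated correlation). Adjusted over the list alone, 2 passed, isg15 and irf7. The interferon list did not pass without control 3 (camera adjusted p = 0.336) or at a mean RPKM of at least 2 (camera adjusted p = 0.207). Without knockout 3, 5 of the 11 members were positive (camera adjusted p = 0.0438). Endocrine pancreas genes had a median of 0.20 over 11 members (camera adjusted p = 0.00835, and adjusted p = 0.235 with an estimated correlation). The members with the smallest p were mnx1 and neurod1. Both neurod1 and isl1 were also on the neuron list, so the rise of this list need not come from islets. Kidney genes had a median of 0.33 over 18 members (camera adjusted p = 0.0076, and adjusted p = 0.675 with an estimated correlation). Their medians were 0.01, 0.09 and 0.77 in knockouts 1, 2 and 3, and the list did not pass without knockout 3 (camera adjusted p = 0.18) or at a mean RPKM of at least 2 (camera adjusted p = 0.196). Cartilage and bone genes had a median of 0.43 over 19 members (camera adjusted p = 0.0386, and adjusted p = 0.865 with an estimated correlation). Their medians were -0.17, -0.11 and 1.13 in the same libraries, and without knockout 3 their direction was lower (camera adjusted p = 0.382). The cartilage and bone list also did not pass with the length trend removed (camera adjusted p = 0.0609). The other 26 lists had camera adjusted p between 0.0659 and 0.915.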

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

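The alternatives that sum knockouts 1 and 2, remove the length trend or count annotation terms without knockout 3 were chosen after seeing the data. The 24 called genes had the same direction in each alternative that tested them, which their separation of all knockout from all control libraries nearly fixes. DESeq2 size factors, a mean RPKM of at least 2 and the length offset left the 3 counts of genes within 1.5 times. With no filter 47 genes were higher, 6 lower and 50 at least 2-fold changed; with DESeq2 188, 46 and 171. Leaving out 1 library gave 0 (without control 2) to 165 (without knockout 3) genes higher, 0 to 41 lower and 0 to 150 at least 2-fold changed, and the cause was not tested. With the pair summed 0 genes were lower by edgeR, against 46 by DESeq2 on 6 libraries. No pairing by replicate number was seen: deviations from the group mean of same-numbered samples correlated at -0.000145, -0.0587 and -0.0348. None of the 3 knockout libraries correlated best with the control of its own number. Knockouts 1 and 2 nearly agree and knockout 3 stands apart, which ties their deviations together, so this cannot decide whether the libraries were paired. The replicate block gave 17 genes higher, 13 of them among the 21, 1 lower, not among the 3, and 18 at least 2-fold changed. Of the lists, 0 passed with an estimated correlation and 4 with fry. The cartilage and bone list, higher with all libraries, was lower without knockout 3, and its adjusted p over the libraries left out ran from 0.00209 to 0.382. Annotation terms numbered 12 without knockout 3. The trdmt1 level stayed lower and short of the threshold in each alternative, with log2 fold changes from -0.40 without control 1 to -1.01 without control 3; the filter at a mean of 2 RPKM removed it. Alternatives meant for RPKM values (pseudocounts, quantile scaling, limma settings, recovered reads) were not run because the table holds counts, and the chromosome test was not run. In simulated data at this spread, with independent libraries and genes of higher counts, 51% of 2-fold changes were recovered, so small changes can be missed.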

Other observations

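Inflammatory genes were higher in the knockout with knockout 3 left out. Leaving out each library was planned, and testing annotation terms in this setting was chosen after seeing the data. This setting rests on knockouts 1 and 2, which nearly agree, so its knockout group can be a single sample and its p-values too small. Among the 165 genes then higher in knockouts 1 and 2, 12 annotation terms were enriched. They were led by inflammatory response (8 genes, among them il1b, ptgs2a, nfkb2, rel and relb; one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.000183) and response to cytokine (adjusted p = 0.000804). The log2 fold change in knockouts 1 and 2 was 2.67 ± 0.21 (SE) for irg1, which makes itaconate in macrophages (edgeR adjusted p = 0.000322) and 1.50 ± 0.14 for tnfaip3, an inhibitor of NF-kB signalling (edgeR adjusted p = 0.0011). It was 1.46 ± 0.17 for rel, an NF-kB subunit gene (edgeR adjusted p = 0.00361) and 2.47 ± 0.13 for ftr86, a fish TRIM gene (edgeR adjusted p = 2.46e-05). In knockout 3 alone against the controls the values were 1.39, -0.43, 0.16 and 0.02, and the difference between knockout libraries was not tested. The 8 genes of the inflammatory response term were all positive in knockout 3, from 0.16 for rel to 2.07 for il1b. Of the 165 higher genes 136 had the same sign in knockout 3, and of the 41 lower genes 22 did. Both comparisons share the 3 controls, which alone favours agreement in sign, and over all genes their log2 fold changes correlated at 0.154. The leukocyte marker list was also higher in this setting, with 17 of 22 positive and a median of 0.21 (camera adjusted p = 0.000285, and adjusted p = 0.582 with an estimated correlation). Relative to the control mean its medians were 0.30 and 0.20 in knockouts 1 and 2, and knockout 2 did not exceed control 1, at 0.22. A change in the number of these cells was not separated from a change within cells. The genes named in this paragraph were picked after their values were seen.

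In knockouts 1 and 2, the cell cycle and neural progenitor lists were also higher. Cell cycle genes had a median log2 fold change of 0.31 with 22 of 23 positive, and neural progenitor genes 0.29 with all 17 positive (camera adjusted p = 0.000166 for both, and adjusted p = 0.582 with an estimated correlation). Relative to the control mean, cell cycle medians were 0.32 in knockouts 1 and 2 and 0.11, -0.24 and 0.15 in controls 1, 2 and 3. Neural progenitor medians were 0.34 and 0.32 in knockouts 1 and 2 and 0.22, -0.25 and 0.02 in the controls. In both lists the controls differed among themselves by more than knockouts 1 and 2 exceeded the highest control. Both rises rest on the same pair of libraries, and in knockout 3 the medians were -0.33 and -0.09. The cone opsin genes given here were chosen after their values were seen. The gene opn1mw1 stood at 25.8, 5.92 and 2.36 RPKM in controls 1, 2 and 3, at 0.200 and 0.310 RPKM in knockouts 1 and 2 and at 86.8 RPKM in knockout 3. The gene opn1sw1 stood at 23.1, 9.23 and 4.89 RPKM in controls 1, 2 and 3, at 0.830 and 1.08 RPKM in knockouts 1 and 2 and at 272 RPKM in knockout 3.

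Of the tests below, those on the differing state of knockout 3, on handling and on a shared pool were chosen after the results were seen; those on heterochronic genes, on other splits and on the neighbours of trdmt1 were written before. Removing the length trend was an alternative chosen after seeing the data, and only what its tests would show was written before their values.

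The rise of immediate early and stress transcription factor genes was weighed first. If the unusual state of knockout 3 had made it, knockouts 1 and 2 would have lain among the controls. In all 21 genes called higher, both lay above the highest control by more than the range of the 3 controls, for fosl1a by 3.32 against a range of 1.50 on the log2 scale. So in these genes the rise was not confined to knockout 3. They were picked as high across the knockout libraries, which nearly fixed this outcome, so it cannot decide the source and they do not stand for others. For the integrated stress response list, the lower of knockouts 1 and 2 lay above the highest control by 0.409 on the log2 scale, more than the range of 0.374 among the controls. This argues against knockout 3 as the source for that list, but the margin is narrow and knockouts 1 and 2 can be a single sample. For the immediate early list the margin was 0.573, less than the control range of 1.22, so for the list as a whole the state of knockout 3 stays open. Without knockout 3 that list had a median log2 fold change of 1.39 with 16 of 18 positive (camera adjusted p = 7.04e-11, and adjusted p = 0.572 with an estimated correlation). A trend with transcript length also does not account for it, since 20 of the 21 were called once each library's trend was removed. Handling or collection of the embryos stays open: the median of the immediate early list ranged over 1.22 on the log2 scale among the 3 controls, so these genes vary without the mutation, and the labels do not say how either group was collected. An effect of the genotype stays open as well and cannot be told apart from handling here.

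The second pattern was the distance of knockout 3 from the other libraries. A trend with length was present, with genes under 1 kb at a median of -0.41 in that library, but it does not account for the tissue genes, since the photoreceptor median was still 1.85 with the trend removed. A candidate explanation is a later developmental stage: the photoreceptor, exocrine pancreas, intestine and cartilage lists lay above all 3 controls and the hatching gland, cell cycle and Hox lists below, but these 7 lists were picked after their values were seen. The test written before, on 9 genes known to fall with age such as lin28a, hmga2 and igf2bp1, gave a median of -0.0718 in knockout 3 against -0.10 to 0.18 in the controls. By the rule as written, a value not below the lowest control spoke against a later stage. It missed that control by less than the range among the controls, so the test was left open, and this margin was set after the value was seen. Stage and an effect of the genotype in this library cannot be told apart, because the labels used here give no age.

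The third pattern was the near agreement of knockouts 1 and 2. Spread was measured beyond that of low-count genes in the same pair, so it can understate the spread beyond counting noise. So measured, the coefficient of variation was 0.109 to 0.143 between controls and 0.207 to 0.257 in pairs with knockout 3. For knockouts 1 and 2 it was 0.00714. This is consistent with libraries made from one pool of embryos or RNA, a hypothesis found and tested on the same data, and the labels do not say. If so, the knockout group would hold 2 independent samples; with the pair summed, 16 genes were higher and 0 lower by edgeR.

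Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 24 called genes, and the highest other gave 1. Most of the other splits set the nearly agreeing knockouts 1 and 2 on opposite sides, which by itself works against calls. The other split with 1 call kept them on the same side. The splits are also too few for a share under 0.05, so they cannot decide whether the count exceeds that of an arbitrary grouping. Of the 50 protein-coding genes nearest to trdmt1 in the GRCz12tu assembly, 25 on each side, 31 were tested here, 62%, which is too few for the test of linked variants to count; 2 of them had an unadjusted p under 0.05, 6.45% against 7.47% of other genes (two-sided Fisher's exact p = 1).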
